A study of Mus musculus with 8 samples.

How the data were processed

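Gene expression was measured by RNA sequencing of whole skin lesions from 8 mice labelled male and 16 weeks old. The deposited table gives a count and an FPKM value for each of 34745 Ensembl genes in every library. The authors made the counts with tools that the labels name as TopHat2 2.0.9, TopHat and HTSeq, without an order or settings, and deposited them as raw whole-number counts per gene. The authors' FPKM values (fragments per kilobase of gene model, scaled to the counts of the library) equalled a constant of each gene times the count over the column total, checked on genes with at least 50 counts. The labels name the builds mm10 and hg38 without a role. Of the gene IDs, 34344 occur in GENCODE release M21 for mm10 (GRCm38), and 27776 of these (80.9%) have the same coordinates there. The annotation release, strand setting and handling of reads that map to several places were not stated.

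Samples were grouped by their labels into NcstnΔKC (4) and normal (4), and replicate numbers were not taken as pairs, because no label says that they pair animals. The replicate block was fitted as an alternative. Genes were filtered with filterByExpr, libraries scaled by the TMM method, and groups compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 15684 genes. Values in CPM are counts over the scaled library size. Gene lists were tested with camera (limma 3.58.1), run on edgeR's count data and dispersions, with a preset correlation of 0.01. They were tested again with an estimated correlation and with fry. Measures of the libraries were compared by an exact two-sided permutation test over 70 arrangements, adjusted over 14 measures. DESeq2 1.42.0 gave other size factors and a Wald test. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

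The comparison, the test, the 41 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 786 entries, of which 782 matched a gene of the table, 4 of them by a synonym. The entries Krt85, Asip, Hbb-b1 and Hbb-b2 were not matched. The rule named the 7 γ-secretase genes, and the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 1 CPM, groups that did not overlap, and a symbol that is not a clone or predicted name. It also named the 4 members of each list with the lowest p, and any other member where a group is described. A few of the genes so named are not reported here. After the data had been seen, 8 more gene lists were added and tested as a family of their own. Of 16 tests of explanations and of other splits of the libraries, 5 were written before their result and 11 after it. The tests on muscle were run together with those on mitochondrial genes and Ncstn. The pattern among ribosome and proteasome subunits was noticed later and was then weighed in place of muscle, whose values are still given.

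Total counts ran from 5835422 to 12893174 per library. A gene with 0 counts in a group was given a bound at a floor of 3 counts over the group, and a gene with 1 to 3 counts a ratio with its 95% counting interval. Intervals and floors cover counting error alone. The common biological coefficient of variation was 0.315. The procedure was tested on simulated data with 15500 genes and 4 libraries per group. There 67 genes were changed 1.5-fold, 68 were changed 2-fold and 63 were changed 4-fold, and the rest were left unchanged. Of these edgeR recovered 4.48%, 13.2% and 87.3% in that order, with 7 of 74 calls false. Camera called the seeded list and 0 of 40 others. DESeq2 made 34 false calls among 135. In the real data 44.1% of genes passed, so the cutoff differed and these rates do not carry over. Genes were simulated without correlation, so the simulated lists do not test the preset correlation.

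Alternatives were upper-quartile, DESeq2 and total-count scaling, limma-voom, the Wald test, no filter, at least 1 CPM in 4 libraries, the replicate block, a log2 change of at least 1, a fit that was not robust, limma-trend on log2 FPKM with 1 added, removal of muscle, adipose and hair genes, and leaving out each library. Chosen after seeing the data were removal of mitochondrial and rRNA-linked genes, thinning to the smallest library, Xist as a covariate, the libraries with or without Xist alone, leaving out NcstnΔKC replicate 1 and normal replicate 2 together, scaling by basal keratinocyte genes, and at least 5 CPM in 4 libraries. Counts per exon and reads were not used here. Shared sequence was measured by 31-base stretches, 1 in 8 sampled, that also occur in another annotated gene.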

Results

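RNA sequencing measured gene expression in whole skin lesions from 8 mice aged 16 weeks, in 2 groups of 4. The group labelled NcstnΔKC carried floxed alleles of Ncstn, which encodes nicastrin, a subunit of the γ-secretase protease, and the Krt14-CreER recombinase. Those mice received tamoxifen at 20 mg per kg per day for 5 days from 8 weeks of age and then every 10 days, to remove Ncstn from keratinocytes. The normal group received corn oil according to the protocol text, which gives it the same genotype, whereas its genotype label reads wildtype. Each library was deposited as counts per Ensembl gene, with 34745 genes in the table. Total counts in normal replicates 1 to 4 were 6753966, 5835422, 8663753 and 8412001. Those in NcstnΔKC replicates 1 to 4 were 11881506, 12598814, 12672706 and 12893174. The group means, 7416286 and 12511550.0, differed by more than the spread between replicates (exact two-sided permutation test, p = 0.0286, the smallest that 70 arrangements allow, and adjusted p = 0.04 over 14 measures of the libraries).

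The comparison asked which genes differ in skin between mice treated to lose Ncstn in keratinocytes and normal mice. Ncstn itself was not lower in the libraries labelled NcstnΔKC, except with scaling by basal keratinocyte genes (-0.86 on the log2 scale). Transcripts of cornification, stress keratins, IL-36 cytokines, alarmins and neutrophils were far higher in them. Transcripts of hair follicle stem cells, adipocytes, skeletal muscle and the mitochondrial genome were lower. As gene lists these passed camera with a preset correlation, while 0 of the 24 lists that did so passed with an estimated one. Krt16, a keratin of stressed epidermis, rose from 12.8 ± 5.7 to 1589.5 ± 525 CPM, and Tslp, an epithelial cytokine, from 1.21 ± 0.161 to 77.9 ± 39.7 CPM (SD, n = 4 each). Lhx2, a transcription factor of follicle stem cells, fell from 42.1 ± 10.2 to 4.7 ± 2.45 CPM. Of 15684 genes tested, 3360 were higher and 3555 lower in the NcstnΔKC libraries at an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Among these 6915 genes, 5882 had groups that did not overlap. Of all tested genes 41.6% had such groups, against 2.86% that chance gives. A change of at least 1 on the log2 scale was seen in 3903 of the changed genes, 1597 higher and 2306 lower. Higher and lower are relative to a median log2 fold change of -0.02 over all tested genes. This median was 0.29 when libraries were scaled by total counts alone, 0.20 with the authors' FPKM and -0.80 when scaled by basal keratinocyte genes, which gave 5323 higher and 2224 lower, 5351 and 2115, and 608 and 8221 genes respectively. The 4 libraries without Xist transcripts alone, 2 against 2, gave 4 genes (BC100530, Lars2, Stfa3 and Tslp, chosen after their values were seen), and the 4 with Xist gave 8387.

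Ncstn (mm10, ENSMUSG00000003458, chromosome 1, 172066013 to 172082795) had 60.7, 61.9, 61.3 and 58.4 CPM (counts scaled to library size by edgeR) in normal replicates 1 to 4. The NcstnΔKC libraries had 66.8, 50.2, 57.8 and 56.2 CPM, in the same order. The means were 60.6 ± 1.54 and 57.7 ± 6.86 CPM (SD, n = 4 each), a log2 fold change of -0.07 ± 0.12 (SE, adjusted p = 0.663). Its 95% interval ran from -0.34 to 0.20, so a fall of over 20.9% lay outside it, and an exact permutation test on log2 CPM gave p = 0.429. The log2 fold change was 0.24 with scaling by total counts, 0.23 with FPKM, and -0.86 with scaling by basal keratinocyte genes. Only the last of these passed the threshold (adjusted p = 0.00538, with a range over 26 alternatives of 0.00538 to 0.999). With that scaling the median of all tested genes was itself -0.80. Counts over the whole gene do not separate the floxed exons from the others. The libraries are therefore named by their label throughout. Of the other γ-secretase subunits, Psenen (ENSMUSG00000036835, chromosome 7, 30561868 to 30563184) rose by 1.23 ± 0.29 on the log2 scale (adjusted p = 0.00841) and Aph1a (ENSMUSG00000015750, chromosome 3, 95893969 to 95898288) by 0.79 ± 0.22 (adjusted p = 0.0162). Psen2 (ENSMUSG00000010609, chromosome 1, 180227004 to 180263438), a presenilin, rose by 0.73 ± 0.19 (adjusted p = 0.0138). With scaling by basal keratinocyte genes these values were 0.43, 0.02 and -0.04, and none of the 3 passed. The call of Psenen also ended in the libraries with Xist alone (0.91). Aph1b (ENSMUSG00000032375, chromosome 9, 66775202 to 66795490, -0.38 ± 0.26) and Aph1c (ENSMUSG00000053040, chromosome 9, 66814994 to 66834726, -0.49 ± 0.30) did not pass, although Aph1b did without normal replicate 3 (-0.53, adjusted p = 0.0392, with a range over alternatives of 0.00667 to 0.98), and both did with scaling by basal keratinocyte genes (-1.14 and -1.22). As a list of 7 genes, γ-secretase did not pass (camera adjusted p = 0.646), with a median of -0.07, a mean of 0.18 and a test pointing up.

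**Figure D1:**
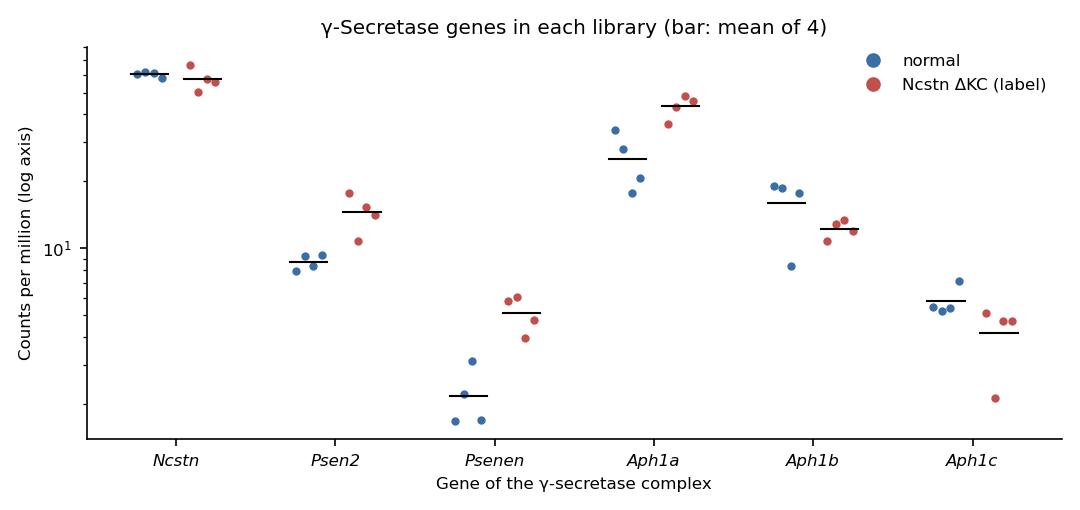
Each point is one library's normalised counts in CPM (log axis) for a γ-secretase gene, in normal (blue) and labelled NcstnΔKC (red) skin, with bars at the mean of 4. Ncstn overlaps between the groups at 60.6 and 57.7 CPM, while Psenen, Psen2 and Aph1a lie higher in the NcstnΔKC libraries, although Psen2 is at -0.04 on the log2 scale with scaling by basal keratinocyte genes.

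Several parts of library composition separated the groups. Genes of the mitochondrial genome took 4.86% ± 0.967 of normal counts and 0.817% ± 0.138 of NcstnΔKC counts (SD, n = 4 each). Gm42418, a locus that collects reads of ribosomal RNA, took 8.20% ± 0.491 and 0.567% ± 0.414, whereas Gm26917, another such locus, took 0.883% ± 0.222 and 4.84% ± 1.46. Basal keratinocyte genes took 1.03% ± 0.228 and 1.76% ± 0.276, and adipocyte genes 0.636% ± 0.0945 and 0.194% ± 0.119. Each of these gave an exact permutation p of 0.0286 (adjusted p = 0.04 over 14 measures). Skeletal muscle genes took 2.42%, 10.5%, 16.8% and 13.6% of counts in normal replicates 1 to 4 and 3.30%, 0.589%, 1.21% and 1.33% in NcstnΔKC replicates 1 to 4 (exact permutation p = 0.0571, adjusted p = 0.0667). Genes of epidermal differentiation (p = 0.743) and of fibroblasts (p = 0.714) showed no difference larger than the spread in this exact test. The first principal component held 60.8% of the variance and separated the groups, and the second (13.5%) set NcstnΔKC replicate 1 apart. All mice were labelled male, but normal replicates 3 and 4 held 24421 and 22304 counts of Xist and NcstnΔKC replicates 3 and 4 held 37109 and 36905, with 0 to 3 counts of Y-linked genes, whereas the other 4 libraries held 4 to 9 Xist counts and 886 to 4453 Y-linked counts.

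**Figure D2:**
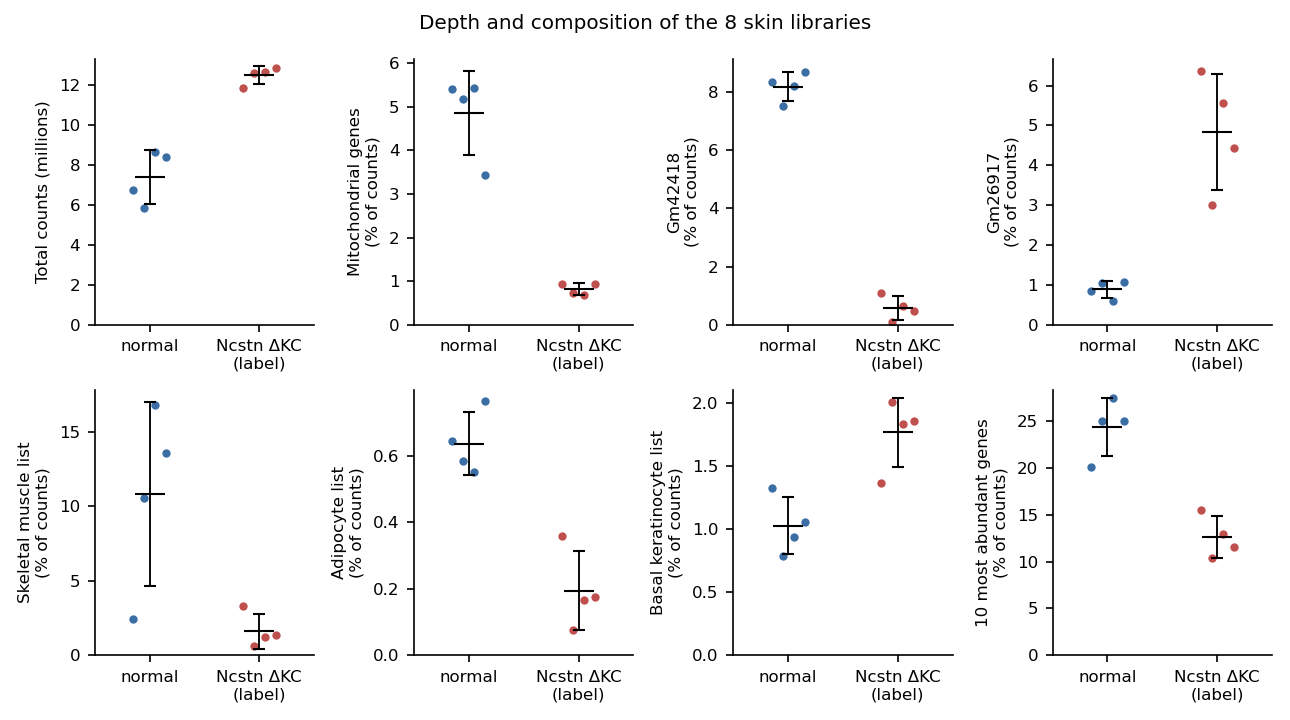
Each panel plots 1 measure of the 8 libraries, in counts or percent of counts, for normal (blue) and labelled NcstnΔKC (red) skin, with the mean and SD of 4 in black. Mitochondrial genes and Gm42418 take more of every normal library, and Gm26917 and basal keratinocyte genes take more of every NcstnΔKC library.

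The 12 largest rises included genes of the cornified envelope, the protein shell of the outermost epidermis. Lce3e (ENSMUSG00000074433, chromosome 3, 92967061 to 92968281), Lce3b (ENSMUSG00000042031, chromosome 3, 92932979 to 92934097) and Lce3f (ENSMUSG00000068885, chromosome 3, 92992226 to 92993426) had 0 counts in normal skin. They were at least 131-fold, 126-fold and 74.3-fold higher, against a floor of 3 counts over the group. NcstnΔKC replicate 1 had the highest values of these genes, and without it the bounds were 57.6, 74.3 and 38.7. Lce3a (ENSMUSG00000054325, chromosome 3, 92925287 to 92926230), with 1 normal count, had a ratio of 214 (95% counting interval 38.1 to 8456). Without NcstnΔKC replicate 1 the Lce3a ratio was 97.5, and without normal replicate 2, which held that count, it was at least 57.8. Sprr2a2 (ENSMUSG00000068893, chromosome 3, 92215920 to 92256724) and Sprr2a1 (ENSMUSG00000078664, chromosome 3, 92215799 to 92221911) had 0 normal counts and were at least 136-fold and 124-fold higher. Their annotated intervals overlap. Sprr2g (ENSMUSG00000046203, chromosome 3, 92373915 to 92375229), with 2 normal counts, had a ratio of 405 (112 to 3349.8). Krt6b (ENSMUSG00000023041, chromosome 15, 101676034 to 101680289), a keratin of wounded epidermis, rose from 1.69 ± 0.948 to 1434 ± 669.8 CPM (SD, n = 4 each), a log2 fold change of 9.71 ± 0.68. Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), a chitinase-like protein of myeloid cells, rose by 9.74 ± 1.34 on the log2 scale. Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283333), a collagenase, rose by 8.41 ± 1.31, a call that limma-voom did not make (7.65). Cbln1 (ENSMUSG00000031654, chromosome 8, 87468854 to 87472592) and Akr1d1 (ENSMUSG00000038641, chromosome 6, 37530173 to 37568815) had 0 normal counts and were at least 133-fold and 20.9-fold higher. Genes with 0 counts in a group were ranked by the fitted log2 fold change (7.61 for Akr1d1), not by the bound, so their rank is uncertain.

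The 12 largest falls included genes of the hair shaft and inner root sheath, which were abundant mainly in normal replicate 2. Tchh (ENSMUSG00000052415, chromosome 3, 93442330 to 93449077), trichohyalin, had -10.55 ± 2.55 on the log2 scale, and -4.75 without normal replicate 2. Its call ended with limma-voom (-6.16), with the replicate block (-5.12) and in the libraries with Xist alone (-5.08). Krt28 (ENSMUSG00000055937, chromosome 11, 99364872 to 99374903), with 3 NcstnΔKC counts, had a ratio of normal to NcstnΔKC of 2129 (728 to 10329). That ratio was 50.6 without normal replicate 2 and 5025 without NcstnΔKC replicate 1, and limma-voom, FPKM and the fit without a filter did not call Krt28. Gabrp (ENSMUSG00000020159, chromosome 11, 33550781 to 33578959), a GABA receptor subunit, had 0 NcstnΔKC counts and was at least 449.9-fold lower, or 222-fold without normal replicate 2. Nnat (ENSMUSG00000067786, chromosome 2, 157560078 to 157562522), with 3 NcstnΔKC counts, had a ratio of 266 (90.5 to 1297), which was 144 without normal replicate 2 and 589.9 without NcstnΔKC replicate 2. Car6 (ENSMUSG00000028972, chromosome 4, 150187015 to 150201332), a secreted carbonic anhydrase, had -6.16 ± 1.42 and -3.18 without normal replicate 2. Acoxl (ENSMUSG00000027380, chromosome 2, 127838876 to 128123873) had -5.82 ± 1.28, with -3.74 without normal replicate 1 and -6.69 without NcstnΔKC replicate 1. FPKM called neither Car6 (-2.32) nor Acoxl (-2.01). Lars2 (ENSMUSG00000035202, chromosome 9, 123366940 to 123462664), the mitochondrial leucyl-tRNA synthetase, had -6.75 ± 0.17, from 1479 ± 84.7 to 13.7 ± 1.26 CPM (SD, n = 4 each), and its share of counts, like that of the locus Gm42418 tied to ribosomal RNA, was lower in every NcstnΔKC library. Scd3 (ENSMUSG00000025202, chromosome 19, 44203288 to 44244016), a stearoyl-CoA desaturase, had -6.32 ± 1.11, and -8.83 without NcstnΔKC replicate 1. Lep (ENSMUSG00000059201, chromosome 6, 29060220 to 29073877), leptin of adipocytes, had -6.19 ± 1.04, a call that ended in the libraries with Xist alone (-5.29), and Plcd4 (ENSMUSG00000026173, chromosome 1, 74542888 to 74567794), a phospholipase C, had -6.16 ± 0.78. The muscle genes Tnnc2 (ENSMUSG00000017300, chromosome 2, 164777161 to 164779967) and Ky (ENSMUSG00000035606, chromosome 9, 102505750 to 102546239) had -5.83 ± 0.93 and -5.82 ± 0.65, and Tnnc2 had -6.82 without NcstnΔKC replicate 1.

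Of 41 gene lists fixed before the data were examined, 24 passed camera with a preset correlation of 0.01 (Benjamini-Hochberg over the lists), 16 higher and 8 lower. With an estimated correlation 0 passed, the lowest adjusted p being 0.186, whereas fry, which asks whether a list moves on balance in 1 direction, called 24, of which 20 were shared. The 4 called by fry alone were those of EGF receptor ligands, Schwann cells, the xenobiotic response and the oestrogen response, and the 4 by camera alone those of epidermal differentiation, sebaceous lipid, other chemokines, and T and NK cells. Of the 35 ways to split the 8 libraries into groups of 4, 7 gave at least 24 lists, the real one among them. Splits that took as many libraries from each group gave 10 to 20. Camera with the preset correlation thus passed many lists also where the group difference was balanced out. The median of every list that passed kept its sign under each scaling tried. The counts of higher and lower members shifted with the scale, and for lists with a larger shift they are given, in that order, when scaled by total counts and by basal keratinocyte genes.

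Transcripts of the cornified layer and of stressed keratinocytes were higher. Within the NcstnΔKC group they parted in replicate 1, which lay above the other 3 libraries in Lce3e (45.8 CPM against 5.64 to 7.47) and below them in Krt16 (805 against 1794 to 1892). In the late cornified envelope and Sprr list 15 of 18 measured members rose and 0 fell (16 adjusted over the list alone, adjusted p = 7.75e-12, and adjusted p = 0.186 with an estimated correlation). Its median log2 fold change was 5.91, also with genes at 0 counts set to their bound, and examples were Sprr2a3 (5.53 ± 0.52) and Lce3c (5.85 ± 0.91, with 7.64 without normal replicate 2 and 5.07 without NcstnΔKC replicate 1). Among 4 stress keratins, induced in wounds and inflamed skin, 3 rose (4 adjusted over the list alone, adjusted p = 1.43e-06, and adjusted p = 0.214 with an estimated correlation). Krt16 went from 12.8 to 1589.5 CPM (6.97 ± 0.45) and Krt6a from 93.4 to 1476 CPM (3.98 ± 0.63, and 4.58 without normal replicate 2). Krt17 had 0.70 ± 0.29 and did not pass, but did without NcstnΔKC replicate 1 (0.93), and was at -0.11 with scaling by basal keratinocyte genes. Of 13 basal keratinocyte genes, 10 rose and 2 fell (12 adjusted over the list alone, adjusted p = 1.79e-04, and adjusted p = 0.23 with an estimated correlation, 11 and 2 scaled by total counts, 5 and 3 by basal keratinocyte genes). Krt14 rose by 2.01 ± 0.24 and the integrin Itga3 by 2.13 ± 0.12, whereas Krt15, also a marker of bulge stem cells, had -2.61 ± 0.36. In epidermal differentiation 16 of 31 members rose and 6 fell (23 adjusted over the list alone, adjusted p = 0.00562, and adjusted p = 0.618 with an estimated correlation, 21 and 5 scaled by total counts, 10 and 9 by basal keratinocyte genes), and the call ended under 3 alternatives (fry, the libraries with Xist, and without both NcstnΔKC replicate 1 and normal replicate 2). Its median went from 1.03 to 0.17 with scaling by basal keratinocyte genes. The repetin gene Rptn rose by 3.08 ± 0.24 and the transglutaminase Tgm1 by 1.54 ± 0.18, while the suprabasal keratins Krt77 (-3.49 ± 0.41) and Krt10 (-2.30 ± 0.44) fell. Of 16 genes of ceramide and barrier lipid synthesis 10 rose and 2 fell (12 adjusted over the list alone, adjusted p = 3.83e-04, and adjusted p = 0.458 with an estimated correlation, 10 and 1 scaled by total counts, 4 and 3 by basal keratinocyte genes), among them Ugcg at 1.98 ± 0.11 and Cers3 at 2.25 ± 0.33, and the call ended in the libraries with Xist alone. The median of this list went from 0.89 to 0.11 when scaled by basal keratinocyte genes. Cers4 had -2.90 ± 0.70, with -2.11 without normal replicate 1 and -3.79 without NcstnΔKC replicate 1.

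Genes of proliferation followed the same direction, with 20 of 30 members higher and 3 lower (25 adjusted over the list alone, adjusted p = 4.61e-05, and adjusted p = 0.458 with an estimated correlation, 22 and 1 scaled by total counts, 3 and 5 by basal keratinocyte genes). Cdk1 (2.06 ± 0.25), Ccnb1 (2.01 ± 0.28) and Pcna (1.26 ± 0.14) rose. Kif23 (-0.85 ± 0.18), a kinesin of cytokinesis, fell. Of 12 EGF receptor ligands and receptors 7 rose and 3 fell, the same number when adjusted over the list alone, but the list did not pass camera (adjusted p = 0.149), whereas fry called it as higher (adjusted p = 0.00113, 7 and 2 scaled by total counts, 4 and 5 by basal keratinocyte genes). Nrg1 (2.76 ± 0.44) rose and Btc (-2.45 ± 0.30) fell.

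**Figure D3:**
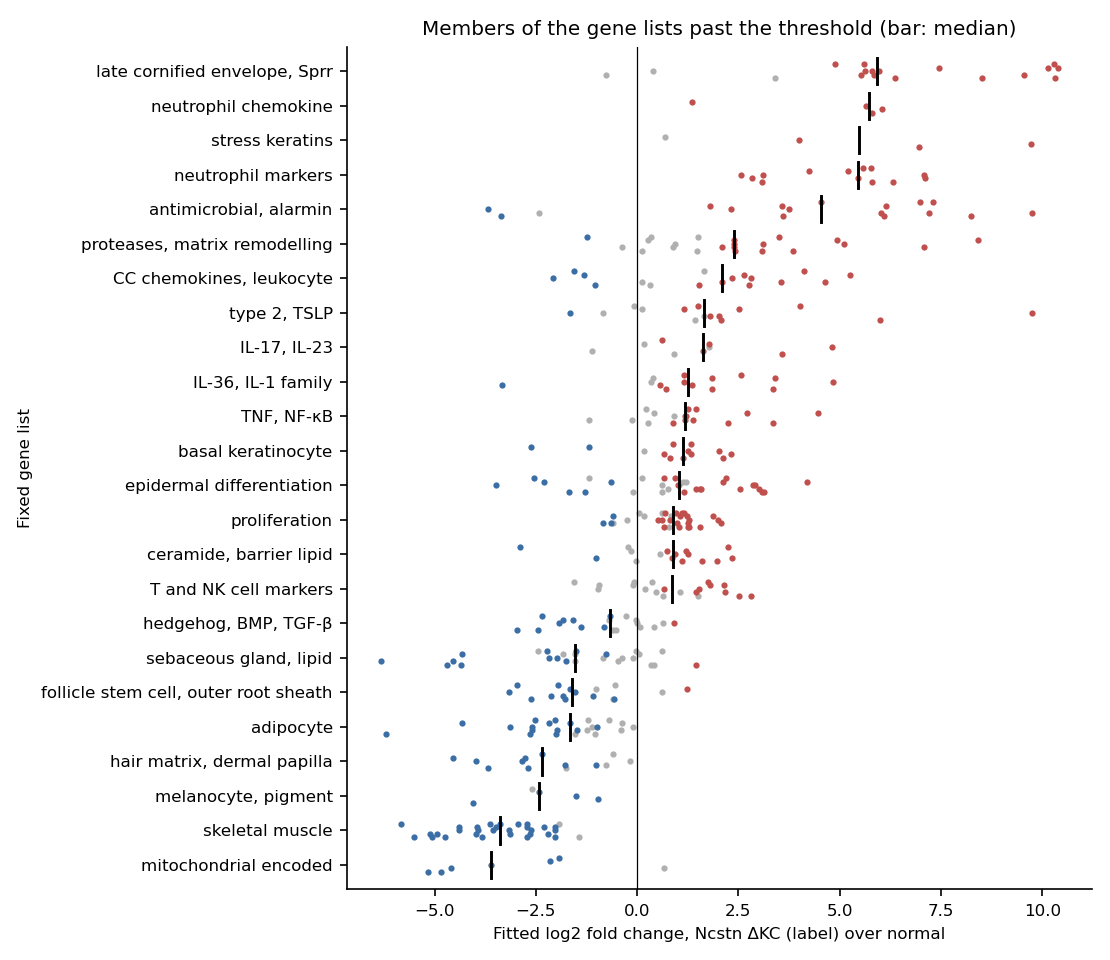
Each point is the fitted log2 fold change of a list member (NcstnΔKC label over normal), coloured where it passed an adjusted p under 0.05, for the 24 lists past the threshold, with bars at the median. Medians run from -3.59 for mitochondrial genes to 5.91 for late cornified envelope and Sprr genes.

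Epidermal cytokines and alarmins were higher in the NcstnΔKC libraries. In the IL-36 and IL-1 family 11 of 14 members rose and 1 fell (12 adjusted over the list alone, adjusted p = 2.19e-04, and adjusted p = 0.186 with an estimated correlation, 12 and 1 scaled by total counts, 6 and 1 by basal keratinocyte genes). The genes of IL-36β (Il1f8, 3.35 ± 0.37, 4.75 to 48.8 CPM) and IL-36γ (Il1f9, 2.57 ± 0.42, 17 to 102 CPM) rose, as did Il1a (1.85 ± 0.31) and Il18 (1.85 ± 0.30). That of IL-36α (Il1f6) rose by 4.84 ± 0.98, or 4.09 without NcstnΔKC replicate 1 and 6.54 without normal replicate 3. Il1f10 alone fell (-3.33 ± 0.45). Of 17 antimicrobial and alarmin genes 14 rose and 2 fell (16 adjusted over the list alone, adjusted p = 3.27e-11, and adjusted p = 0.186 with an estimated correlation). BC100530, a stefin gene, rose by 8.23 ± 0.31 and Lcn2, an iron-binding protein of inflamed epithelium, by 3.56 ± 0.35 (4.63 to 54.9 CPM). S100a8, a calprotectin subunit, rose by 6.09 ± 0.64, or 6.84 without normal replicate 4. Defb6 (-3.36 ± 0.51) and Wfdc21 (-3.68 ± 0.56, and -4.47 without NcstnΔKC replicate 4) fell. In the IL-17 and IL-23 list 5 of 9 members rose (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.00468, and adjusted p = 0.28 with an estimated correlation), among them Il17rc (1.62 ± 0.19) and Zc3h12a (1.78 ± 0.38). In the type 2 list 9 of 15 rose and 1 fell (11 adjusted over the list alone, adjusted p = 2.53e-04, and adjusted p = 0.28 with an estimated correlation). Tslp, an epithelial cytokine of type 2 inflammation, rose from 1.21 to 77.9 CPM (5.99 ± 0.46), its receptor subunit Crlf2 by 2.07 ± 0.46 and Il4ra by 2.53 ± 0.36. In the TNF and NF-κB list 11 of 17 rose (11 higher and 1 lower adjusted over the list alone, adjusted p = 1.19e-05, and adjusted p = 0.243 with an estimated correlation, 12 and 0 scaled by total counts, 5 and 1 by basal keratinocyte genes), including Icam1 (2.23 ± 0.17) and Nfkb1 (1.18 ± 0.12). Its median of 1.19 was 0.45 when scaled by basal keratinocyte genes.

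**Figure D4:**
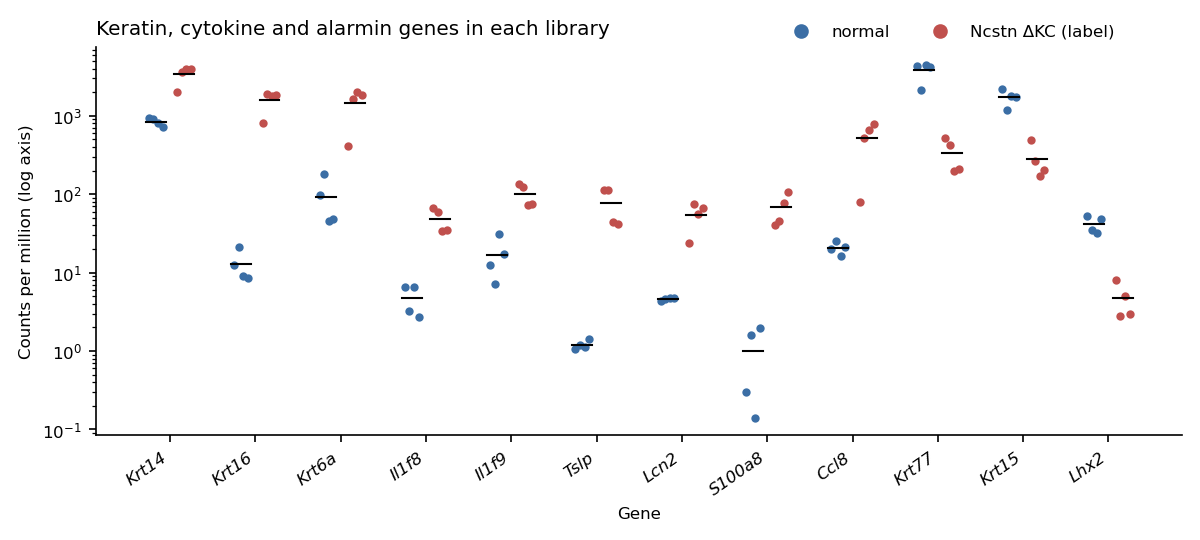
Each point is one library's normalised counts in CPM (log axis) in normal (blue) and labelled NcstnΔKC (red) skin, with bars at the mean of 4, for list members picked after their values were seen. Tslp rises from 1.21 to 77.9 CPM and Krt16 from 12.8 to 1589.5 CPM, while Krt77, Krt15 and Lhx2 are lower in the NcstnΔKC libraries.

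Transcripts of neutrophils and of their chemokines were also higher. All 4 measured neutrophil chemokine genes rose (4 adjusted over the list alone, adjusted p = 0.00231, and adjusted p = 0.186 with an estimated correlation), such as Cxcl1 at 1.36 ± 0.37. All 13 measured neutrophil genes rose (13 adjusted over the list alone, adjusted p = 2.90e-09, and adjusted p = 0.243 with an estimated correlation), such as Mmp8 (7.09 ± 0.91) and Hdc (4.24 ± 0.56), although 1 entry, Il1f9, is an epidermal cytokine. Among 17 other chemokines 10 rose and 4 fell (14 adjusted over the list alone, adjusted p = 0.0371, and adjusted p = 0.54 with an estimated correlation), and the call ended under 7 alternatives, among them without normal replicate 1 and without normal replicate 2. Ccl8 rose from 20.7 to 515 CPM (4.64 ± 0.63) and Ccl2 by 2.76 ± 0.56, while Ccl27a, a keratinocyte chemokine, had -2.16 ± 0.53. Of 20 T and NK cell genes 9 rose (9 adjusted over the list alone, adjusted p = 0.0206, and adjusted p = 0.567 with an estimated correlation, 11 and 0 scaled by total counts, 5 and 3 by basal keratinocyte genes), among them Icos (2.52 ± 0.27) and Cd4 (2.17 ± 0.36), with a median of 0.86 that was 0.16 when scaled by basal keratinocyte genes, and 5 alternatives did not call the list (total-count scaling, limma-voom, fry, a minimum of 5 CPM, and the libraries without Xist). Of 22 proteases and inhibitors 13 rose and 1 fell (16 adjusted over the list alone, adjusted p = 5.71e-09, and adjusted p = 0.186 with an estimated correlation), with Klk8 at 2.42 ± 0.17 and Adam8 at 3.51 ± 0.35, while the inhibitor Timp3 had -1.24 ± 0.20. Macrophage and dendritic cell genes went both ways, 9 higher and 5 lower of 22 (17 adjusted over the list alone, adjusted p = 0.304, 13 and 4 scaled by total counts, 2 and 6 by basal keratinocyte genes). Mrc1 (2.34 ± 0.52) and Cd14 (2.89 ± 0.52) rose, while Flt3 (-2.10 ± 0.34) and Clec9a (-2.27 ± 0.44), both of dendritic cells, fell. The lists of B and plasma cells (4 higher of 7, 5 adjusted over the list alone, adjusted p = 0.0969, 5 and 0 scaled by total counts, 1 and 0 by basal keratinocyte genes) and of mast cells, basophils and eosinophils (4 higher and 1 lower of 7, 6 adjusted over the list alone, adjusted p = 0.085, 5 and 0 scaled by total counts, 1 and 1 by basal keratinocyte genes) did not pass camera or fry.

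Follicle and gland transcripts were lower. Of 16 genes of follicle stem cells and the outer root sheath 11 fell and 1 rose (15 adjusted over the list alone, adjusted p = 1.19e-05, and adjusted p = 0.243 with an estimated correlation), and they overlap the basal keratinocyte list at Krt15. Cd34 (-1.78 ± 0.16), Lhx2 (-3.17 ± 0.37), Sox9 (-1.66 ± 0.20) and Lgr5 (-1.54 ± 0.26) fell, and Fzd10 (1.24 ± 0.26) rose. In hair matrix and dermal papilla 9 of 13 fell (10 adjusted over the list alone, adjusted p = 0.00201, and adjusted p = 0.4 with an estimated correlation), for example Wnt10b (-2.68 ± 0.38) and Gata3 (-1.01 ± 0.17), and the call ended with a minimum of 5 CPM. Lef1 had -4.55 ± 0.89, and -3.05 without normal replicate 2, where hair shaft genes took 3.88% of counts against 0.0031% to 0.0463% in the other normal libraries. The hair shaft list itself had 4 of 5 measured members lower (4 adjusted over the list alone) and did not pass (adjusted p = 0.301). Of 25 sebaceous and lipid genes 11 fell and 1 rose (12 adjusted over the list alone, adjusted p = 0.034, and adjusted p = 0.619 with an estimated correlation, 3 and 9 scaled by total counts, 1 and 17 by basal keratinocyte genes). That call ended under 6 alternatives, among them without normal replicate 1, without NcstnΔKC replicate 2 or 4, and without muscle, adipose and hair genes. The list shares Scd1, Cidea, Dgat2 and Pparg with the adipocyte list, so its fall is not separate from that of adipocyte genes. Pparg (-1.96 ± 0.36) fell. Of 5 melanocyte genes 4 fell (5 adjusted over the list alone, adjusted p = 0.0371, and adjusted p = 0.458 with an estimated correlation), such as Mitf (-0.97 ± 0.19), and the call ended under 3 alternatives, among them without NcstnΔKC replicate 1. In the hedgehog, BMP and TGF-β list 9 of 19 fell and 1 rose (10 adjusted over the list alone, adjusted p = 0.0242, and adjusted p = 0.503 with an estimated correlation), with Gli1 at -2.95 ± 0.39 and Bmp4 at -1.94 ± 0.33. The call ended under 5 alternatives, among them without normal replicate 1, without normal replicate 2, and without muscle, adipose and hair genes. In the Wnt list 5 of 21 rose and 9 fell (14 adjusted over the list alone, adjusted p = 0.994, 7 and 5 scaled by total counts, 3 and 11 by basal keratinocyte genes). Wnt10a (3.01 ± 0.16) and Wnt4 (1.56 ± 0.12) rose, and Axin2 (-0.71 ± 0.15) fell.

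Transcripts of deeper tissue and of mitochondria were lower as well. Of 31 skeletal muscle genes 29 fell (31 adjusted over the list alone, adjusted p = 4.73e-09, and adjusted p = 0.458 with an estimated correlation), including Pgam2 (-5.06 ± 0.70) and Neb (-3.39 ± 0.69). The muscle share of normal replicate 1, at 2.42%, was below that of NcstnΔKC replicate 1. Of 23 adipocyte genes 14 fell (16 adjusted over the list alone, adjusted p = 1.64e-04, and adjusted p = 0.458 with an estimated correlation), among them Fabp4 (-2.52 ± 0.50) and Plin1 (-2.66 ± 0.65). Of 7 measured mitochondrial genes 6 fell (6 adjusted over the list alone, adjusted p = 2.55e-08, and adjusted p = 0.186 with an estimated correlation), from mt-Nd6 (-1.92 ± 0.24) and mt-Co1 (-2.15 ± 0.26) to mt-Nd2 (-4.84 ± 0.35). The lists of fibroblasts, endothelium and Schwann cells did not pass camera, but fry called the Schwann cell list as lower (adjusted p = 0.0251). In the fibroblast list 8 of 25 rose and 2 fell (10 adjusted over the list alone, adjusted p = 0.37, 9 and 2 scaled by total counts, 1 and 7 by basal keratinocyte genes), with Tnc, tenascin C of wound stroma, at 4.15 ± 0.89 (5.29 without normal replicate 2) and Dcn at -1.06 ± 0.23. In the endothelial list 3 of 14 rose and 3 fell (7 adjusted over the list alone, adjusted p = 0.77, 7 and 1 scaled by total counts, 0 and 7 by basal keratinocyte genes), and in the Schwann cell list 3 of 10 fell (3 adjusted over the list alone, adjusted p = 0.085, 0 and 2 scaled by total counts, 0 and 9 by basal keratinocyte genes). None of 7 red cell genes changed (adjusted p = 0.963, 1 and 0 scaled by total counts, 0 and 2 by basal keratinocyte genes), and 0 adjusted over the list alone. Slc4a1 and Hbb-bs, named after their values were seen, had an unadjusted p under 0.05. The list's median of 0.17 and mean of 0.09 differed in sign from the test.

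The Notch pathway, whose receptors are substrates of γ-secretase, did not pass as a list by camera (adjusted p = 0.784) or fry (adjusted p = 0.835), with 5 of 20 members higher and 2 lower (7 adjusted over the list alone), a median of 0.05 and a mean of -0.02. Scaling by basal keratinocyte genes gave 1 higher and 10 lower with a median of -0.77, against -0.80 over all genes. Scaling by total counts gave 8 higher and 2 lower with a median of 0.36, against 0.29 over all genes. The target genes Nrarp (-1.64 ± 0.13, adjusted p = 1.04e-04) and Hes1 (-1.41 ± 0.27, adjusted p = 0.00365) fell, while the ligands Dll1 (1.91 ± 0.21) and Jag2 (1.14 ± 0.18) rose. Hey1 had -1.11 ± 0.52 (adjusted p = 0.114) and passed without NcstnΔKC replicate 1 (-1.59). In the type I interferon list 2 of 25 rose and 4 fell (2 adjusted over the list alone, adjusted p = 0.516, 3 and 2 scaled by total counts, 0 and 11 by basal keratinocyte genes), including Ifit3 at -2.48 ± 0.36. In the interferon-γ and MHC list 6 of 22 rose and 4 fell (10 adjusted over the list alone, adjusted p = 0.571, 7 and 2 scaled by total counts, 1 and 6 by basal keratinocyte genes), with Cxcl10 at 2.60 ± 0.55 and the MHC class II genes Cd74 (-1.52 ± 0.31) and H2-Aa (-1.01 ± 0.21) lower. Of 18 xenobiotic response genes 7 rose and 2 fell (10 adjusted over the list alone, adjusted p = 0.0995, 9 and 1 scaled by total counts, 2 and 5 by basal keratinocyte genes), among them Ahr (1.48 ± 0.18) and Gsta4 (3.07 ± 0.47). The list did not pass camera, but fry called it as higher (adjusted p = 8.84e-04). In the oestrogen response list, of interest because tamoxifen was given to 1 group, 1 of 13 rose and 3 fell (4 adjusted over the list alone, adjusted p = 0.374, 4 and 2 scaled by total counts, 1 and 8 by basal keratinocyte genes), with Igfbp5 at -3.71 ± 0.25. It did not pass camera, but fry called it as lower (adjusted p = 0.0157). Its median was -0.36 and its mean 0.00, and both tests pointed down. Of 20 immediate early genes 4 rose and 2 fell (6 adjusted over the list alone, adjusted p = 0.382, 4 and 0 scaled by total counts, 1 and 8 by basal keratinocyte genes), with Ier3 at 2.35 ± 0.25. Their median was -0.19 and their mean 0.01, and the test pointed up.

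The groups differ in tamoxifen as well as in the intended deletion, and no label gives a sequencing batch or date, so that these cannot be told apart from the deletion. The Sprr2, Lce3 and stefin families hold near-identical genes, and how reads shared between copies were counted is not stated.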

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

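The tests on the direction of subunits with little shared sequence, on length and GC content among the subunits, on strand and on splits of the libraries were chosen before their results were seen, and those on mitochondrial genes, Ncstn, muscle, the trend on length and GC content over all genes, and the spread of subunits with little shared sequence only after.

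Genes of the mitochondrial genome had a median log2 fold change of -3.59 in the libraries labelled NcstnΔKC, where Gm42418 took less and Gm26917 more of the counts. Less of a mitochondria-rich tissue would lower nuclear genes of the respiratory chain by about as much, but their median was -0.37 with an SD of 1.11. More ribosomal RNA kept in every normal library, alike at both loci, would lower Gm26917 too, but it rose by 2.15 on the log2 scale. That argues only against a like change at both loci. The mean share of counts (NcstnΔKC minus normal) differed by -7.63 percentage points for Gm42418 and 3.96 for Gm26917. More ribosomal RNA in total in the normal libraries therefore stays open. A library preparation that differed along the groups could account for the pattern and cannot be told apart from them, since all 8 libraries lay on their own group's side of an equal share of these loci and no label gives a batch. An effect of the deletion or of tamoxifen stays open and was not tested.

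Ncstn was not lower in the libraries labelled NcstnΔKC, except with scaling by basal keratinocyte genes (-0.86, against a median of -0.80 over all genes). Reads from exons outside the deleted part could account for this and cannot be told apart from a deletion that did not occur, because counts cover the whole gene, with a lower 95% bound of -0.34 for its log2 fold change. A swap of some libraries between the groups is argued against, as 0 of the 8 libraries correlated best with a library of the other group, and correlations were at most 0.852 between the groups and at least 0.920 within them. This covers a swap after library preparation. If preparation differed along the groups, an earlier swap of mice or tissue could leave the same correlations. An exchange of the labels of both whole groups would leave these correlations as they are. It cannot be told apart from correct labels by Ncstn either, with an upper 95% bound of 0.20. Cells of whole skin outside the reach of Krt14-CreER also stay open, without a test.

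Within the ribosome, and within the proteasome, subunits moved in opposite directions. Of 77 ribosome subunits 31 were higher and 14 lower, and of 31 proteasome subunits 11 were higher and 5 lower. Together 42 were higher and 19 lower of 108 tested, but 64 and 13 with scaling by total counts and 1 and 46 with scaling by basal keratinocyte genes. Mixed directions also held over all tested genes, of which 44.1% changed, 48.6% of these higher. For the proteasome, reads shared with near-identical annotated copies are argued against as the source of the spread among subunits, because its 17 subunits with under 5% shared sequence had an SD of log2 fold changes of 0.61 (95% bootstrap interval 0.42 to 0.77), against 0.56 among the other 14 and a median SE of 0.14. For the ribosome such reads cannot be told apart from other sources, since only 2 of its subunits have so little shared sequence. Whether shared reads set the directions also stays open, as 8 of these 19 subunits were higher and 4 lower. A bound of 5 in each direction, set beforehand, decides nothing where 3.34 lower ones would be expected at the rate of all subunits. Gene length and GC content are argued against as the source of the spread, because among the 108 subunits they gave an R² of 0.0359 (95% bootstrap interval 0.00242 to 0.147). That 96.7% of the called subunits (59 of 61) were still called without the trend over all genes decides nothing, since that trend had an R² of 0.00995 and moved them by a median of 0.067, less than their median SE of 0.15. A strand setting that differed along the groups is argued against too, because 16.4% of the called subunits have exons overlapped on the other strand, against 30.1% of all protein-coding genes. A biological difference between the groups stays open and was not tested.

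The muscle share of the highest normal library was 6.94 times that of the lowest, against 6.75 between the group means, but without normal replicate 1, the lowest, it was 1.596 times that of the lowest of the other 3. Without muscle, adipose and hair genes 6951 genes changed, and 95.3% of the calls were shared. In only 1 of 35 splits of the 8 libraries into groups of 4, the real one, did as many as 6915 genes change. The highest other, which parts the libraries by Xist, gave 5 (Ddx3y, Eif2s3y, Kdm5d, Uty and Xist, chosen after their values were seen). A chance division of the libraries is thus argued against for this count, though 35 splits allow no share below 1 in 35. Any difference that runs along the labels, such as library preparation, would give the same result. For gene lists chance is not excluded by this count, as 7 of the 35 splits, the real one among them, gave at least 24 and the highest other gave 31. The others that did so held 3 libraries of the same group and so kept part of the group difference. Splits that took as many libraries from each group, and so balanced out the group difference, still gave 10 to 20 lists.

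Of 372 groups of 4 values, over 177 genes and the measures of the libraries, 50 held a library far from its group by Dixon's ratio, 13.4% against about 1 in 20 by chance. The ratio was taken on log2 CPM with 1 added for genes and on plain values for the measures. That chance rate holds for independent groups, and genes of the same library are not independent. NcstnΔKC replicate 1 held 22 of the 50 and normal replicate 2 held 15. NcstnΔKC replicate 1 lay above the other 3 libraries of its group in Lce3e at 45.8, Lce3f at 23.5, Lce3a at 24.4, Scd3 at 7.38, Lce1g at 119.9, Krt32 at 1.34, Krtap3-2 at 6.13, Tcf7l1 at 6.63 and Zc3h12a at 115 CPM. NcstnΔKC replicate 1 lay below the other 3 libraries of its group in Krt6b at 460.4, Nrarp at 10.2, Krt14 at 2038, Krt16 at 805, Krt6a at 408, Krt17 at 509, Nrg1 at 6.38, H2-Aa at 54.5, Cxcl10 at 3.44, Cpa3 at 24.2, Ear2 at 0.42, Thbs2 at 258 and Gsta4 at 13.3 CPM. NcstnΔKC replicate 2 lay below the other 3 libraries of its group in Aph1c at 2.12, Icos at 8.2, Vwf at 84.2 and Gli1 at 1.16 CPM. Normal replicate 1 lay above the other 3 libraries of its group in Cxcl3 at 0.456 CPM. Normal replicate 1 lay below the other 3 libraries of its group in Plcd4 at 1.82, Il1r1 at 60.7 and Tpm1 at 396 CPM. Normal replicate 2 lay above the other 3 libraries of its group in Lce3a at 0.202, Gabrp at 76.8, Car6 at 166, Tgm1 at 114, Krt32 at 49.996, Krtap3-2 at 301, Tnc at 149, Mitf at 77.6 and Wnt4 at 39.9 CPM. Normal replicate 2 lay below the other 3 libraries of its group in Krt77 at 2117, Degs2 at 2.02, Cxcl10 at 2.22, Zc3h12a at 8.47 and Flt3 at 3.02 CPM. Normal replicate 3 lay above the other 3 libraries of its group in Ltf at 0.565 CPM. Normal replicate 3 lay below the other 3 libraries of its group in Aph1b at 8.33 CPM. Normal replicate 4 lay above the other 3 libraries of its group in Aph1c at 7.17 CPM. Normal replicate 4 lay below the other 3 libraries of its group in Cxcl1 at 0.912 CPM. Mitochondrial genes took 3.42% of counts in normal replicate 4, below the 5.19% to 5.43% of the other normal libraries. Hair shaft and inner root sheath genes took 3.88% of counts in normal replicate 2, above the others.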

How the results depend on the processing

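Alternatives based on Xist, thinning, removal of mitochondrial genes, the pair of libraries that stand apart, basal keratinocyte genes and at least 5 CPM were chosen only after the data were seen. The count of 6915 changed genes was within 1.5 times in 26 of 28 alternatives, the exceptions being a log2 change of at least 1 and the libraries without Xist. It was 6937 with DESeq2's size factors, 6887 with upper-quartile scaling, 7503 with the Wald test, 6698 with limma-voom, 7254 without a filter, 5981 with the replicate block, 6934 with a fit that was not robust, 6951 without tissue genes, 6902 without mitochondrial and rRNA-linked genes, 6335 after thinning, and 6874 with Xist as a covariate. At least 5 CPM left 12239 genes, of which 5718 changed, and at least 1 CPM in 4 libraries left the same genes as the main filter and tested nothing. Leaving out 1 library gave 5619 to 7994 genes, 2733 to 3870 higher, 2722 to 4124 lower, and 22 to 29 gene lists. Without NcstnΔKC replicate 1 and normal replicate 2 together 8028 genes changed. A count within 1.5 times need not hold the same genes. Of the 6915 calls, 5584 were also made in the same direction with scaling by total counts and 5446 with FPKM. Scaling by basal keratinocyte genes, with 8829 genes changed, shared 4163.

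Scaling by total counts gave 5323 higher and 2224 lower genes, limma-trend on FPKM 5351 and 2115, and scaling by basal keratinocyte genes 608 and 8221. The first and last of these change the scale alone, which moved the median of all genes to 0.29 and -0.80. The FPKM alternative, with a median of 0.20, also scales by total counts. FPKM here equals a constant of each gene times its count over the column total. That alternative changes the test and the transformation as well, and their part in its shift was not tested. With basal keratinocyte scaling Ncstn was at -0.86 and passed, and Psen2 turned to -0.043. A log2 change of at least 1 left 3903 genes by its construction, 1597 higher and 2306 lower. The 4 libraries without Xist gave 4 genes, 3 higher and 1 lower, while the 4 with Xist gave 8387. Those without Xist include both libraries that stand apart, NcstnΔKC replicate 1 and normal replicate 2. The cause of that contrast was not tested. With an estimated correlation 0 gene lists passed of the 24. The correlations estimated for these lists ran from 0.077 (IL-36 and IL-1 family) to 0.94 (stress keratins), all above the preset of 0.01. Only the correlation option was changed, so the 24 calls rest on the low preset. Of all values under alternatives for named genes and lists, those above included, 1633 kept their side of the threshold, 99 lost a call, 39 gained one and 1 reversed. A change of sign was counted as reversed only where the main fit or the alternative called the value, so uncalled values may have changed sign. Depth limits what can be seen for genes near the floor of 3 counts over a group.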

Other observations

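All 8 gene lists described here were chosen only after the data were seen, and their adjusted p values cover these 8 lists. Nuclear genes of the respiratory chain were lower, with 33 of 85 members lower and 6 higher (adjusted p = 2.19e-04, and adjusted p = 0.91 with an estimated correlation). Their median of -0.37 was -0.07 with scaling by total counts (13 higher and 23 lower) and -1.19 with scaling by basal keratinocyte genes (0 higher and 67 lower). Ndufb10 (-2.97 ± 0.25 on the log2 scale) and Ndufb3 (-2.72 ± 0.21), subunits of complex I, and Cox5b (-1.88 ± 0.20), of complex IV, fell, while Cox8a (1.27 ± 0.23) rose. In glycolysis 6 of 16 members rose and 1 fell (adjusted p = 0.0041, and adjusted p = 0.91 with an estimated correlation), with a median of 0.25 that was -0.55 with scaling by basal keratinocyte genes (4 higher and 5 lower, against 8 and 0 with total counts). The glucose transporter gene Slc2a1 rose from 52.9 to 386 CPM (2.86 ± 0.17), Eno1 by 2.02 ± 0.18 and Pgam1 by 1.54 ± 0.17. Of 77 ribosomal protein genes 31 rose and 14 fell, and the list passed camera (adjusted p = 0.0326, and adjusted p = 0.91 with an estimated correlation) but not fry (adjusted p = 0.0598), with a median of 0.38 that was -0.39 with that scaling (1 higher and 32 lower, against 44 and 9 with total counts). Rps7 (1.80 ± 0.13) rose, while Rpl21 (-2.52 ± 0.19) and Rpl38 (-1.84 ± 0.17) fell.

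The other 5 of the added lists did not pass camera or fry. Of 31 proteasome genes 11 rose and 5 fell (adjusted p = 0.244), or 20 and 4 with scaling by total counts and 0 and 14 with scaling by basal keratinocyte genes, with Psmb4 at 1.46 ± 0.18 and Psma4 at -1.05 ± 0.12. Of 17 clock genes 2 rose and 6 fell (adjusted p = 0.244), or 3 and 3 with scaling by total counts and 0 and 10 by basal keratinocyte genes, and Bhlhe41, a repressor of the clock, fell from 36.7 to 2.85 CPM (-3.69 ± 0.37). Of 21 genes of desmosomes and cell junctions 5 rose and 5 fell (adjusted p = 0.704), or 9 and 3 with scaling by total counts and 1 and 11 by basal keratinocyte genes. Dsg3, the desmoglein of the lower epidermis, rose by 1.44 ± 0.14, while periplakin, Ppl (-1.43 ± 0.25), and desmoplakin, Dsp (-0.91 ± 0.18), fell. Of 18 genes of the unfolded protein response 2 rose and 1 fell (adjusted p = 0.244), or 10 and 1 with scaling by total counts and 0 and 3 by basal keratinocyte genes, with Ddit3 at -1.14 ± 0.24. Of 19 cholesterol synthesis genes 1 rose and 2 fell (adjusted p = 0.967), or 3 and 1 with scaling by total counts and 1 and 10 by basal keratinocyte genes, with Ebp at 1.53 ± 0.28, and the test pointed up although the median of -0.11 and mean of -0.14 were negative.

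Xist and Y-linked genes parted the libraries in a way that cut across the groups and differed from the label of male for all 8 mice. The libraries correlated at 0.928 to 0.969 within normal, 0.920 to 0.987 within NcstnΔKC and 0.818 to 0.852 between the groups (Pearson's r across genes, which are not independent replicates).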
